A study of Homo sapiens with 9 samples.

How the data were processed

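Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in T47D, a human breast cancer cell line of luminal type that carries the oestrogen receptor. Per the labels, 9 samples fell into 3 groups of 3: cells with a control short hairpin RNA (shCtrl) in normoxia, the same cells in hypoxia, and cells with a hairpin against ZHX2 (shZHX2) in hypoxia. The oxygen level and the length of the hypoxia were not given in the sources used here. Per the labels' protocols, nuclei were transposed with a Nextera kit and the libraries were sequenced as paired ends on an Illumina NovaSeq.

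The files analysed were 3 lists of called regions, 1 per group, each deposited without a header and in a broad-peak layout of 9 columns. FastQC, Bowtie2, SAMtools, MACS2 and the genome build hg38 are named in the submitters' processing notes, without versions or settings. How the 3 samples of a group were combined into 1 list, and whether read positions were shifted for the transposase, were not given in the sources used here. In each deposited list the authors gave every region a score, a fold enrichment over the local background, a −log10 p and a −log10 q. From the values, the score is 10 times the −log10 q cut to a whole number in nearly every region, and every region has a −log10 p above 10. These values are the authors' own and were used here to describe, rank or match regions within a list. They also served to recover a background level for each list and to project hypoxia regions to the shZHX2 level. No file holds values per sample, so a group has 1 list, no spread between replicates could be computed and no p-value is given for any comparison. Wilson 95% intervals stand beside shares of regions and cover counting error only. Regions are not replicates, so such an interval says nothing of how far another culture would differ.

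The number of reads behind each list is not known. A background level was recovered for each list from the pairs of fold enrichment and −log10 p of its narrow autosomal regions, under the Poisson test of the peak caller with an assumed pseudocount of 1. The lower quartile of these levels was 23.3 for normoxia, 24.7 for hypoxia with shCtrl and 19.8 for hypoxia with shZHX2. With the pseudocount taken off, the normoxia and shZHX2 levels were 94.3% and 79.2% of the hypoxia shCtrl level.

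Regions of 2 lists that shared at least 1 bp counted as called in both. Regions of a list did not overlap one another, so none had to be merged within a list. A region counted as called only under one condition when no region of the other list touched it. Gene positions came from a RefSeq gene table of GRCh38.p14, which shares its coordinates with hg38 and holds 20046 protein-coding genes on the chromosomes used. It gives the start and end of each gene and not its strand or its exons. The plan fixed before the data were examined used transcription start sites, so it was adapted to gene ends: a region lay at a gene end when it touched the 1 kb on either side of the start or the end of a protein-coding gene, and it was assigned to the gene whose nearer end lay closest, within 50 kb. One of the 2 ends is the annotated start of transcription, and promoters inside a gene are not counted. Motif searches for 18 fixed consensus sequences and matching on GC content had been planned and were not run, because no genome sequence was used here.

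For each set of regions called in 1 list of a pair, the number of members of 14 gene lists with at least 1 such region was compared with 10000 random gene lists of the same size, matched on the number of regions assigned to each gene. The percentile among them describes these lists of regions and is not a test of the conditions. All 291 list members were found in the gene table, 2 of them through an older symbol, and 1 of the 291, MIR210HG, is not protein-coding and entered only the counts of gene ends. The gene lists held HIF targets, oxygen sensing and ZHX family genes, luminal and oestrogen receptor genes, mesenchymal, invasion and basal genes, AP-1 and stress response factors, NF-kB targets, interferon response genes, cell cycle genes, respiratory chain genes, chromatin architecture genes, housekeeping genes, and markers of blood, of stroma and endothelium, and of liver and neuron. The number of regions expected from score was computed by giving each region of a list the rate of its score decile. This second measure, lists cut to equal length for the gene lists, and gene-end shares of regions matched on score, fold and width were added after the data were seen.

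The share of hypoxia-only regions that were also not called with shZHX2 was set against 1000 draws of hypoxia regions that normoxia shares, matched on score decile. Both comparisons use the hypoxia shCtrl list, so unchanged lists were also simulated: 1 strength per site, the same noise in each list, and a threshold that gives each list its observed length. The noise was set once from the share of hypoxia regions called in normoxia and once from the share called with shZHX2.

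Genes were named by a rule fixed before the data were examined. For each comparison and direction it takes the 5 regions with the highest fold in their own list that lie over 1 kb from any region of the other list, with 1 region per gene, the 5 genes with the most regions, and up to 4 members of each gene list. It always takes ZHX2, HIF1A, CA9, VEGFA and ESR1, and the 10 genes with the most regions among hypoxia-only regions not called with shZHX2. A gene named outside it is said to be so, and some genes are not reported here. The alternatives tried were a 50% overlap, a distance of 500 bp, lists cut to the length of the shortest by score or by fold, the stronger 50% of a list, chromosomes 1 to 22 and X only, a gene-end window of 2 kb, assignment within 20 kb, random lists without matching, no matching or matching also on gene-end status for the shared regions, and 50 score bins. The code was tested on simulated data. From a copy of the hypoxia list with regions removed, 100% of the removed regions were found as not called, a planted difference of 20 points came back as 19.1, and 3% of 100 unchanged gene lists passed the 97.5th percentile. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.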

Results

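Accessible chromatin was mapped in T47D breast cancer cells in normoxia, in hypoxia, and in hypoxia with ZHX2 knocked down. ZHX2 is a zinc finger and homeobox transcription factor, and the series asks what it does to chromatin when oxygen is low. The list for normoxia with shCtrl held 90962 regions that covered 60.1 Mb. The list for hypoxia with shCtrl held 77451 regions over 48.5 Mb, and the list for hypoxia with shZHX2 held 62779 regions over 40.6 Mb. Median widths were 496, 463 and 474 bp. Each group of 3 samples gave 1 list, so no difference below has a replicate check, and "called" means past the authors' threshold in that list.

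Most accessible sites were shared. Merging the lists gave 97804 regions, of which 57100 (58.4%) were called in all 3. These shared regions held most of the gene ends: 23.4% of them touched the end of a protein-coding gene, against 2.89% to 4.96% of the regions called in 1 or 2 lists. Normoxia alone had 16354 regions, normoxia and hypoxia shCtrl together had 14973, and hypoxia shCtrl alone had 4249. Another 2389 regions were called in normoxia and with shZHX2 but not in hypoxia with shCtrl, 2005 were called only with shZHX2, and 734 were called in both hypoxia lists but not in normoxia. In all 3 lists, 13935 protein-coding genes had a region at an end.

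**Figure D1:**
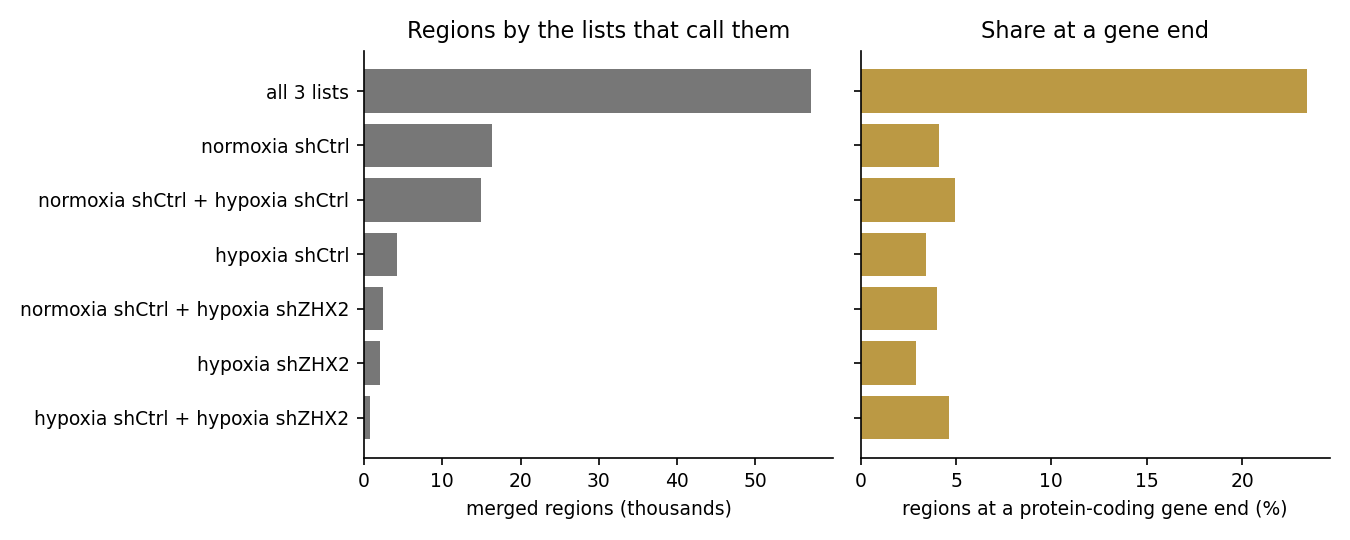
Merged regions by the combination of lists that call them (left) and the share of each combination at a protein-coding gene end (right, %). The 57100 regions called in all 3 lists are the largest class, and 23.4% of them lie at a gene end, against at most 4.96% in any other class.

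ZHX2, HIF1A and VEGFA were accessible at a gene end in every list, and CA9 was not. The start of ZHX2 itself was called in each list, at chromosome 8, 122780078 to 122781496 in hypoxia with shCtrl, and ZHX2 had 10 assigned regions in normoxia, 9 in hypoxia and 8 with shZHX2. Accessibility at its own gene does not report on the knockdown, which lowers RNA, so the labels could not be checked in this way. HIF1A, the oxygen-regulated subunit of HIF-1, had a region at a gene end in all 3 lists. VEGFA, the angiogenic growth factor induced by HIF, was called over its start in all 3 and had 11, 11 and 8 assigned regions in normoxia, hypoxia and hypoxia with shZHX2. CA9, a carbonic anhydrase often used as a marker of hypoxia, had no region at a gene end and none assigned to it in any list.

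Most hypoxia response genes had a region at a gene end in normoxia as well as in hypoxia. Of 40 genes known as HIF targets or hypoxia response genes, 36 had a region at a gene end in normoxia, and the same number in each hypoxia list; CA9, SLC2A3, PFKFB4 and KDM3A had none in any list, of which SLC2A3 and PFKFB4 fall outside the naming rule. All 25 cell cycle genes, all 19 chromatin architecture genes and all 22 housekeeping genes had one in each list. The counts were equally flat for 10 of 11 oxygen sensing and ZHX genes, 17 of 18 AP-1 and stress factors and 12 of 14 interferon response genes. Of all 20046 protein-coding genes, 14869 had a region at a gene end in normoxia. Among markers of other cell types, it was 7 of 14 blood markers in normoxia and 6 in each hypoxia list, 6, 5 and 4 of 12 stroma and endothelium markers in normoxia, hypoxia and hypoxia with shZHX2, and 5 of 10 liver and neuron markers in each. Over the 14 lists, 255 of 291 members had a gene end called in normoxia, 247 in hypoxia and 248 in hypoxia with shZHX2.

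A few list members differed at a gene end, and these were picked out after their calls were seen. TFF1, a secreted trefoil peptide induced by oestrogen, was called at its end in normoxia and in neither hypoxia list, and so were ZEB2 and TWIST2, transcription factors of the mesenchymal programme, CD68 and COL6A3. CXCL8 and CCL2, chemokines under NF-kB control, were called at an end in normoxia and with shZHX2 but not in hypoxia with shCtrl. CD3D and PDGFRA were called in both shCtrl lists only, and CSF1R with shZHX2 only.

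Hypoxia was compared with normoxia in shCtrl cells to find sites that open or close when oxygen falls. Hypoxia-only regions lay near HIF targets about as often as near genes of random lists. Among HIF targets PDK1, a mitochondrial kinase that inhibits pyruvate dehydrogenase, had the most, with 3 of its 6 hypoxia regions absent from normoxia. These lay at 172686348 to 172686631, 172688985 to 172689194 and 172693129 to 172693519 on chromosome 2, all within the span of the gene. They were 37681, 35118 and 30793 bp from its nearer end, and the region by its other end was called in all 3 lists. The largest number for any gene was 4, at ETS1, a transcription factor of the ETS family, PTPRT, a receptor tyrosine phosphatase, NFASC, a neuronal adhesion protein, CAMK2B, a calcium-dependent kinase, and the uncharacterised LOC101929601. The numbers expected from score were 2.43 at ETS1, 0.647 at PTPRT, 1.65 at NFASC, 1.33 at CAMK2B and 0.850 at LOC101929601. The strongest hypoxia-only regions with a gene end within 50 kb lay by SRD5A3 (chromosome 4, 55328096 to 55328348, fold 6.17 in its list), FAM3B, VCF2, PRKG1 and IL1RAP.

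By gene list, 8 of 39 HIF targets had a hypoxia-only region, against a mean of 7.12 in matched random lists (percentile 65.8); besides PDK1 they included ANGPTL4, the glucose transporter gene SLC2A1 and LOX, each with 1. Cell cycle genes had 6 of 25, among them TOP2A, RRM2, MCM5 and PLK1 (percentile 96.7). Luminal genes had the lowest percentile of the 14 lists, with 3 of 30, at GRHL2, GATA3 and ELF3, against a random mean of 8.17 (percentile 0.975). That percentile was 37.5 with random lists that were not matched on the number of regions. It was 46.2 among the stronger hypoxia regions, of which only 45 were hypoxia-only. The percentile stayed low with lists of equal length by score, at 0.325 with 4 luminal genes, and with assignment within 20 kb, at 0.575. Against the number of regions expected from score it was 1.88. With lists of equal length by fold 13 luminal genes had a hypoxia-only region, and no percentile is given for that count. Other lists lay within the central 95% of their random lists: oxygen sensing and ZHX genes with 2 of 11, mesenchymal, invasion and basal genes with 6 of 32, AP-1 and stress factors with 2 of 18, NF-kB targets with 2 of 20, interferon response genes with 1 of 14, respiratory chain genes with 2 of 24, chromatin architecture genes with 3 of 19, housekeeping genes with 2 of 22, and markers of blood, of stroma and endothelium, and of liver and neuron with 0 of 14, 1 of 12 and 2 of 10.

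In the other direction, many more regions were called in normoxia and not in hypoxia, and the progesterone receptor gene PGR had the most of any gene. Of 18 normoxia regions assigned to PGR, 12 were not called in hypoxia, 6 hypoxia regions remained, and the region over one end of the gene was called in all 3 lists. The number expected at PGR from the scores of its regions was 7.93. RREB1, a zinc finger transcription factor, had 9 normoxia-only regions, and KCNK5, a potassium channel, UGCG, which makes glucosylceramide, and SLC39A11, a zinc transporter, had 8 each. From score 5.77 were expected at RREB1, 2.99 at KCNK5, 5.20 at UGCG and 4.63 at SLC39A11. KCNK5 also lay near one of the strongest normoxia-only regions with a gene end within 50 kb (chromosome 6, 39251319 to 39251900, fold 6.82), as did ZNF736, CPPED1 and SYMPK.

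Luminal genes held 58 normoxia-only regions in 22 of 30 members: after PGR came NRIP1, a corepressor of the oestrogen receptor, and GRHL2, an epithelial transcription factor, with 5 each, and ESR1, the oestrogen receptor gene, with 4 of its 11 normoxia regions. The count of 22 lay near the random mean of 21.2 (percentile 62.1). HIF targets had 19 of 39, with CA12 and STC2 at 3 regions each (percentile 41.8), and NF-kB targets had 10 of 20, led by NFKBIA with 6 and IRF1 with 4 (percentile 81.7). Mesenchymal, invasion and basal genes had 17 of 32, led by TWIST2 and CD44 with 4 each, AP-1 and stress factors had 12 of 18, and oxygen sensing and ZHX genes had 8 of 11, with EPAS1 and ARNT2 at 3 each. Interferon response genes had 2 of 14, cell cycle genes 7 of 25, respiratory chain genes 4 of 24, chromatin architecture genes 8 of 19, housekeeping genes 8 of 22, blood markers 5 of 14, stroma and endothelium markers 7 of 12, and liver and neuron markers 2 of 10. None of the 14 lists lay outside the central 95% of its random lists for normoxia-only regions; with random lists that were not matched 4 did, with luminal genes at percentile 100.

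**Figure D2:**
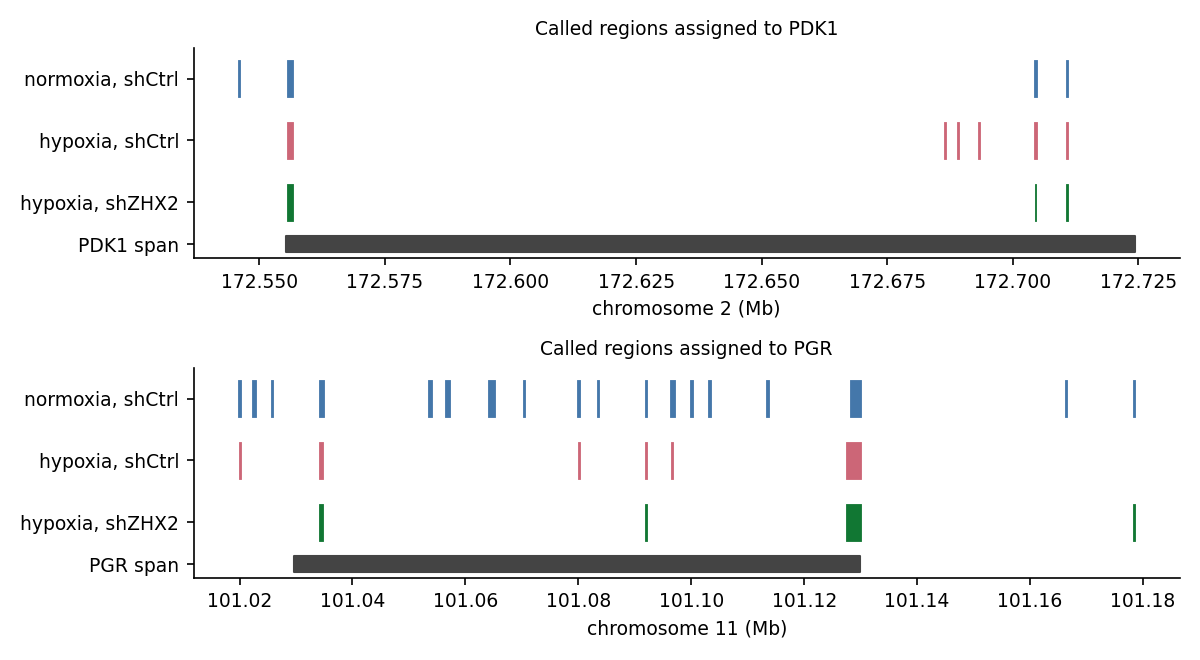
Called regions assigned to PDK1 (upper) and PGR (lower) in each list, along the chromosome in Mb, with the span of each gene as a dark bar; narrow regions are drawn slightly wider than scale. In hypoxia with shCtrl PDK1 has 3 regions that neither other list has, and PGR has 18 regions in normoxia, 6 in hypoxia and 4 in hypoxia with shZHX2.

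In total, 4984 of the 77451 hypoxia regions were not called in normoxia (6.44%, 95% interval 6.26 to 6.61), and 18752 of the 90962 normoxia regions were not called in hypoxia (20.6%, 20.4 to 20.9). Regions called under one condition were rarely at a gene end: 3.59% of hypoxia-only regions, against 5.54% of shared regions of the same scores, and 4.10% of normoxia-only regions, against 5.13%. Matched on fold and width as well, the shared regions had 4.62% and 4.71%. At gene ends, 469 genes had a region in normoxia and not in hypoxia, and 95 the reverse. Both sets came from the weak end of their lists, where 73.4% of the lowest score decile of normoxia was not called in hypoxia, against 0.308% of the seventh decile. In the stronger 50% of each list, 274 normoxia regions were not called in hypoxia and 45 hypoxia regions were not called in normoxia. With lists cut to the length of the shZHX2 list by score, which balances the counts by construction, 6735 regions were hypoxia-only and 6875 normoxia-only, and PGR had 1 normoxia-only region.

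**Figure D3:**
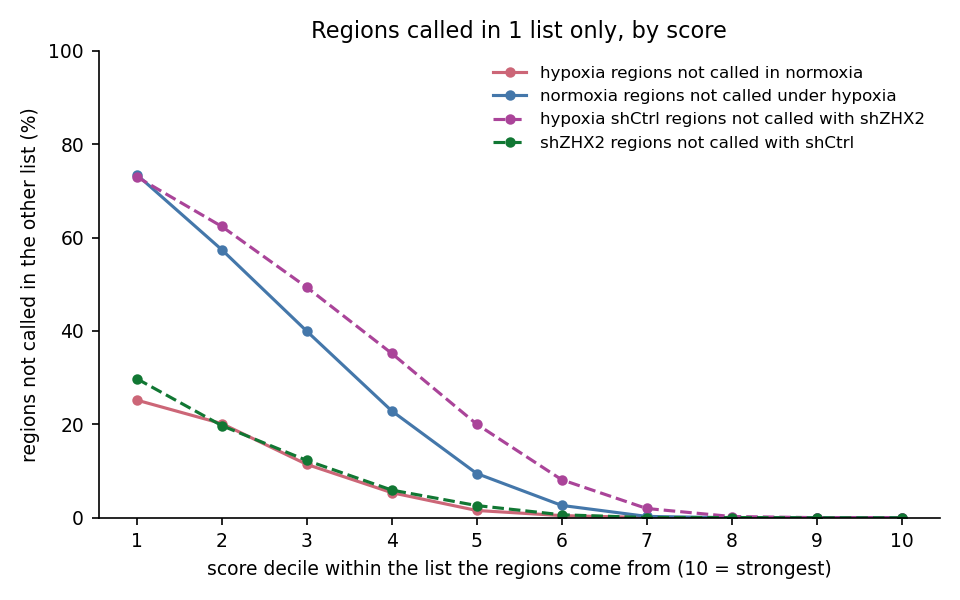
Share of regions not called in the other list (%), by score decile within the list the regions come from, for both directions of hypoxia against normoxia (solid) and of shZHX2 against shCtrl in hypoxia (dashed). In the lowest decile 73.4% of normoxia regions and 73.0% of hypoxia shCtrl regions are missing from the other list, and in the top decile at most 0.0387% in any of the 4 comparisons.

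ZHX2 knockdown was compared with shCtrl in hypoxia to find sites whose accessibility depends on ZHX2. Genes with the most hypoxia regions not called with shZHX2 were ELFN1 with 10, RBM19, which acts in ribosome assembly, and TRPS1, a GATA-type repressor of luminal breast cells, with 9 each, and TMEM132B and the tyrosine kinase gene SRC with 8 each. The numbers expected from score were 8.22 at ELFN1, 5.62 at RBM19, 9.53 at TRPS1, 4.88 at TMEM132B and 5.16 at SRC. VEGFA, the glycolytic regulator PFKFB3 and the hypoxia-induced repressor BHLHE40 each lost the call of 4 regions, where 4.32, 2.86 and 1.94 were expected from score. The 3 regions assigned to PDK1 and called in hypoxia but not in normoxia were also not called with shZHX2. Among uncalled regions with a gene end within 50 kb, the strongest lay near PLEK (chromosome 2, 68357931 to 68358352, fold 8.45 in its list), ANKRD55, the olfactory receptor gene OR1E1, the serotonin receptor gene HTR4 and CRYM.

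Regions not called with shZHX2 were spread over the gene lists about as in random lists. They fell at 19 of 39 HIF targets (random mean 20.3, percentile 30.7), 7 of 11 oxygen sensing and ZHX genes with EPAS1 at 3, 19 of 30 luminal genes led by GRHL2 with 5, and 16 of 32 mesenchymal, invasion and basal genes, where COL5A1 had 4 and TWIST2, SPARC and SNAI1 had 3 each. They also fell at 10 of 18 AP-1 and stress factors, with KLF4 at 4, 6 of 20 NF-kB targets, 3 of 14 interferon response genes, 8 of 25 cell cycle genes, 5 of 24 respiratory chain genes, 8 of 19 chromatin architecture genes, 8 of 22 housekeeping genes, and 4 of 14 blood, 5 of 12 stroma and endothelium, and 2 of 10 liver and neuron markers. None of the 14 counts lay outside the central 95%; 1 did with random lists that were not matched, that of luminal genes (percentile 99.9), and 2 with assignment within 20 kb.

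Regions called only with shZHX2 were fewer and gathered at luminal genes. TRPS1 had the most, 5, and MLLT3, KIF16B, STRBP and MECOM had 4 each. From score 2.34 were expected at TRPS1, 0.771 at MLLT3, 1.17 at KIF16B, 0.715 at STRBP and 1.42 at MECOM. These genes were picked for their counts, and TRPS1 had 19 assigned regions in hypoxia with shCtrl and 15 with shZHX2. Of 30 luminal genes, 15 had a shZHX2-only region, against a random mean of 7.94 (percentile 99.9): GRHL2 had 3, ESR1 and GREB1, an oestrogen-induced growth gene, had 2 each, and NRIP1 had 1. Of the 19 luminal regions, 14 had also been called in normoxia. NF-kB targets had 6 of 20, against 2.32 (percentile 98.8), with 3 regions at IRF1 and 1 each at CXCL8, CD83 and NFKBIA; the CXCL8 region, at 73740472 to 73740835 on chromosome 4, covered the start of the gene and was also called in normoxia. With regions assigned within 20 kb these percentiles were 89.6 and 95.6, and with lists of equal length 92.7 and 87.3. Over the 4 sets and 14 lists, 3 of 56 percentiles lay outside the central 95%, where 2.80 would if percentiles were spread evenly. Some small counts cannot reach the lower tail: 0 of 14 blood markers for hypoxia-only regions was percentile 16. The 2.80 is therefore approximate.

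Other gene lists held few shZHX2-only regions: 4 of 39 HIF targets, with KDM3A at 2, 2 of 11 oxygen sensing and ZHX genes, 4 of 32 mesenchymal, invasion and basal genes, 2 of 18 AP-1 and stress factors, 2 of 14 interferon response genes, 2 of 25 cell cycle genes, 2 of 24 respiratory chain genes, 2 of 19 chromatin architecture genes, 3 of 22 housekeeping genes, 1 of 14 blood markers, and 0 of 12 stroma and endothelium and 0 of 10 liver and neuron markers. Among such regions with a gene end within 50 kb, the strongest lay near TSPAN12, UBE2G2, CDH7, SESN1 and SLC24A4, with folds of 6.37 to 6.62 in their list.

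**Figure D4:**
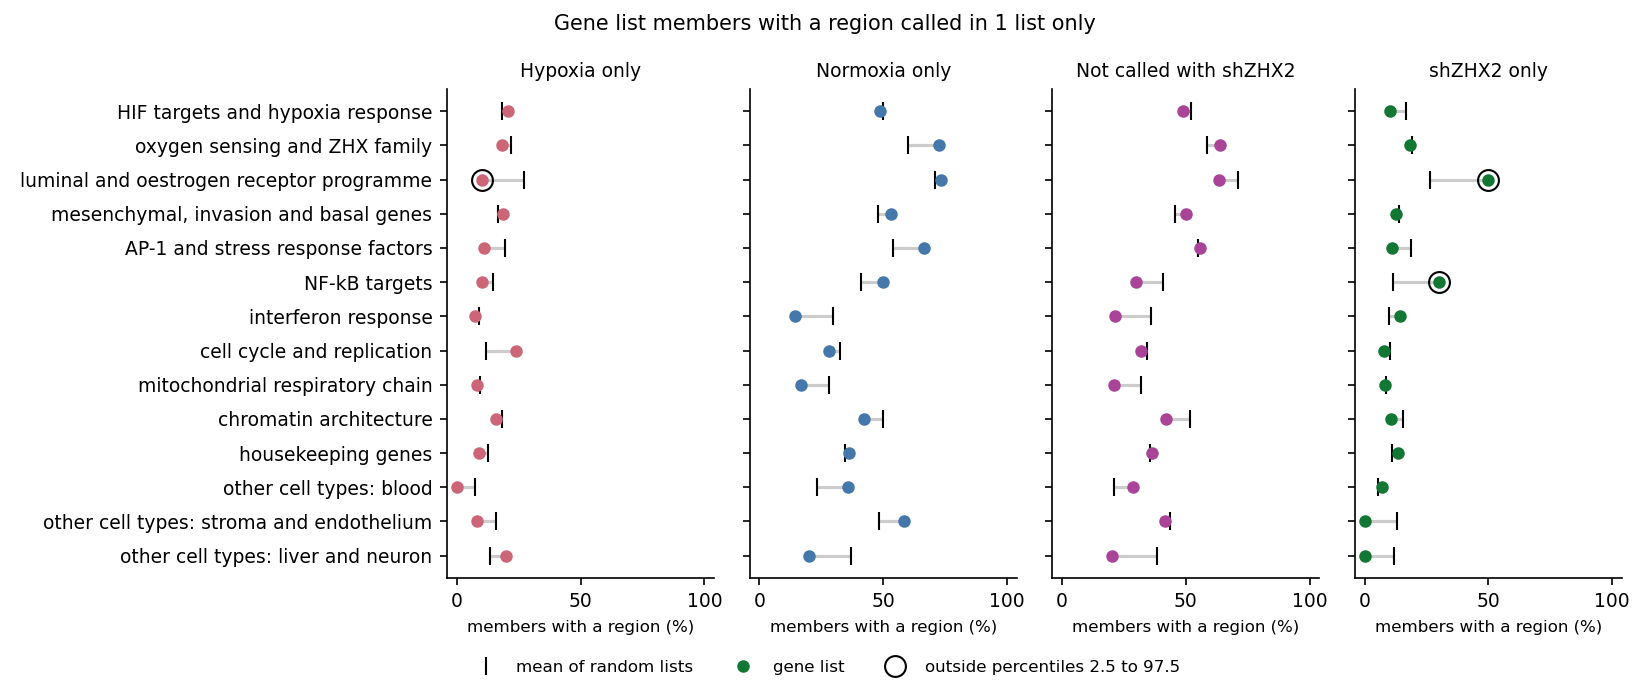
Share of the members of each gene list with at least 1 region called in 1 list of the pair only (%, dots), beside the mean of 10000 random gene lists matched on the number of regions (ticks), for the 4 sets of regions; circled dots lie outside the central 95% of random lists. Luminal genes are circled at 3 of 30 for hypoxia only and 15 of 30 for shZHX2 only, and NF-kB targets at 6 of 20 for shZHX2 only.

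Altogether 19400 of the 77451 hypoxia shCtrl regions were not called with shZHX2 (95% interval 24.7% to 25.4%), and 4466 of the 62779 shZHX2 regions were not called with shCtrl (7.11%, 6.92 to 7.32). At a gene end lay 4.52% of the former, against 6.43% of retained regions of the same scores, and 3.27% of the latter, against 6.67%. Matched on fold and width as well, these shares were 5.08% and 6.02%. A region at a gene end was lost with shZHX2 at 544 genes and gained at 94. In the stronger 50% of each list, 816 hypoxia shCtrl regions were not called with shZHX2 and 49 shZHX2 regions were not called with shCtrl. With lists cut to equal length by score, which balances the counts by construction, they were 9378 and 9099. The shZHX2 list was the shortest and had the lowest background level.

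The lists were then combined to ask whether sites that appear in hypoxia are those that need ZHX2. With no shZHX2 group in normoxia, an effect of the hairpin in hypoxia alone cannot be told from one at any oxygen level. Of the 4984 hypoxia-only regions, 4249 (85.3%, 84.2 to 86.2) were not called with shZHX2. Genes with the most of them were PTPRT and CAMK2B with 4, and PDK1, SLAMF1, PTPRJ, CYP2C19, RBM19, PPDPFL and TNN with 3 each. They fell at 7 of 39 HIF targets, against a random mean of 6.31 (percentile 63.3). Hypoxia regions shared with normoxia and of the same score were not called with shZHX2 in 55.4% (SD 0.670 over draws), a difference of 29.8 points. Simulated lists with no change at any site gave differences of 31.7 and 32.5 points, and the observed difference did not exceed them. Their noise was set from the overlaps of the same lists, so a real change at some sites would count as noise. Within the hypoxia shCtrl list, independent sets of 4984 and 19400 regions would share 1248, a number that does not allow for score. Conversely, 2398 of the 18752 normoxia-only regions (12.8%, 12.3 to 13.3) were called again with shZHX2 in hypoxia; FGD4, MECOM, the growth factor gene HGF, KIF16B, CPEB4, TRPS1 and CBFA2T3, from a set outside the naming rule, had 3 each.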

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

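Lists cut to equal length by fold, score bins of 50, the threshold at the shZHX2 background, and for gene lists the numbers expected by score and lists of equal length were chosen after the data were seen. An overlap of 50%, a distance of 500 bp or leaving out chromosomes other than 1 to 22 and X moved no count of regions by over 1.5 times. List length and the threshold did. With lists of equal length by score, 6875 regions were normoxia-only, 9378 hypoxia regions were not called with shZHX2 and 9099 were shZHX2-only; by fold there were 7800 hypoxia-only, 7895 normoxia-only, 10950 not called with shZHX2 and 10721 shZHX2-only. In the stronger 50% of a list against the whole other list, 45 regions were hypoxia-only, 274 normoxia-only, 816 not called with shZHX2 and 49 shZHX2-only. With the stronger 50% of both lists these were 1387, 8186, 8803 and 1389. Lists of equal length leave nearly equal counts in both directions by construction, so that balance says nothing on the cause of an excess. The share of hypoxia-only regions not called with shZHX2 exceeded that of shared regions by 64.3 points with no matching and by 25.8 points with lists of equal length.

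With a gene-end window of 2 kb, 6.60% of hypoxia-only, 6.97% of normoxia-only, 7.54% of uncalled and 6.14% of shZHX2-only regions lay at a gene end. In the stronger 50% the shares were 6.67%, 3.28%, 5.64% and 4.08%, of only 45, 274, 816 and 49 regions. The number of the 14 gene lists outside the central 95% of random lists was 1, 0, 0 and 2 for hypoxia-only, normoxia-only, uncalled and shZHX2-only regions. With random lists that were not matched it was 0 for hypoxia-only, 4 for normoxia-only and 1 for uncalled regions. With assignment within 20 kb it was 2 for uncalled and 0 for shZHX2-only regions, and in the stronger 50% it was 0 for shZHX2-only regions, of which 49 were left. With regions counted against the number expected by score it was 3, 2, 2 and 4, and with lists of equal length 1 for normoxia-only, 1 for uncalled and 1 for shZHX2-only regions. The cause of these moves was not tested.

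Of 220 counts of regions at named genes, 95 stayed within 1.5 times with lists of equal length, 67 were 0, and 192 were 0 in the stronger 50%. No paired analysis was possible because each group of 3 samples, whose replicate numbers match across groups, has 1 list and no values per sample; leaving out a replicate could not be run for the same reason. Motif shares and their alternatives were not run, since no genome sequence was used here. Depth limits every count near the threshold, and a region that was not called may still be open: 1926 hypoxia regions would fall under the threshold at the shZHX2 background, and 17894 of 19400 uncalled regions would not.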

Other observations

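All tests of explanations in this part, the score-based counts and the comparisons of gene density and chromosomes were chosen after the results were seen; the percentiles of member counts were planned for the 4 sets of regions at full list length, and those for another set and for lists of equal length were not. These tests took the place of an earlier set that was also written after the results. The earlier depth test asked whether at least 50% of the 19400 uncalled regions would fall under the threshold at the shZHX2 background; 1506 did (7.76%), which its rule read as against fewer reads, and it was dropped because the projection leaves out noise. A second compared gene-end shares with regions matched on score, fold and width (−3.76 SD for uncalled regions) and was dropped because all 4 sets lay below their matched shares. The third pattern was at first the normoxia-only regions of luminal genes, by the score-based percentile given next, and was changed to a planned percentile.

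Allowing for score, normoxia-only regions were more numerous than expected at luminal genes, with 58 where 46.5 were expected (percentile 99.7), and at NF-kB targets, with 21 where 15.5 were expected (percentile 98.9). The 58 were 17 with lists of equal length by score (member percentile 83.5) and 26 by fold, where 23 were hypoxia-only. Without PGR, luminal genes had 46 where 38.6 were expected (percentile 98.0). Regions called in normoxia and with shZHX2 but not in hypoxia with shCtrl fell at 11 of 30 luminal genes, against a random mean of 5.83 (percentile 99.5), and at 5 of 20 NF-kB targets, against 2.18 (percentile 97.7). This set largely re-counts shZHX2-only regions that were also called in normoxia, of which luminal genes held 14. It is no separate support for their gathering at these genes. By the score-based count 11 of 56 combinations of gene list and set lay outside the central 95%, among them chromatin architecture genes, with 10 uncalled regions where 16.0 were expected with shZHX2 (percentile 2.42).

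Sites called only with shZHX2, only in hypoxia or only in normoxia lay in gene-poorer surroundings than shared sites of the same score. The shZHX2-only sites had on average 8.71 protein-coding genes within 500 kb, against 10.99 (SD 0.154 over draws) for shZHX2 regions of the same score shared with shCtrl. Hypoxia-only regions had 9.57 against 10.6 and normoxia-only regions 10.01 against 10.6, while regions not called with shZHX2 had 10.4 against 10.3. The number of shZHX2-only regions relative to that expected by score was 0.553 on chromosome 19, 0.640 on chromosome 22 and 0.670 on chromosome 16, and 1.43 on chromosome 13 and 1.32 on chromosome 6. Regions not called with shZHX2 went the other way, with 1.11 on chromosome 19, 1.10 on chromosome 16 and 0.884 on chromosome 6. Hypoxia-only regions were also low on chromosomes 19 and 22, at 0.796 and 0.843. They were at 1.01 on chromosome 16, and low on chromosomes 13 and 6, at 0.858 and 0.892. Regions were not matched on GC content, and whether it differed between the lists was not tested. The strongest region called in hypoxia with shCtrl and in neither other list was 200 bp wide, at 90173338 to 90173537 on chromosome 2, with a fold of 24.8 and no protein-coding gene end within 50 kb. Its width was the smallest in that list. On chromosomes 1 to 22 and X, the next hypoxia-only region over 1 kb from any normoxia region had a fold of 6.63. No filter for regions prone to mapping errors was applied here, so this region may not reflect open chromatin.

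The first pattern weighed is the loss of 19400 hypoxia calls with shZHX2 against 4466 gained. Fewer reads behind the shZHX2 list may account for part of it: its background level was 79.2% of that with shCtrl, and hypoxia regions that would fall under the threshold at that level make up 13.1% of the shortfall of 14672 regions (up to 26.0% at other quantiles of the levels), a projection without noise that excludes nothing. For no change at any site, only a shorter list and noise, the 816 lost regions of the stronger 50% lie between the 368 and 841 lost in simulated unchanged lists, but the noise that gave 841 also gave 800 uncalled normoxia regions where 274 were observed, and the noise that gave 302 of these gave the 368, so no single noise level gave both. The simulations also gave 7 and 45 shZHX2-only regions in the stronger 50%, where 49 were observed, and called 97.9% and 96.3% of all shZHX2 regions in normoxia, where 95.6% were, so unchanged lists with equal noise do not give every value, and a noisier shZHX2 list was not simulated. Closing of sites that need ZHX2 stays open and cannot be told apart from fewer reads, because 1 list per group ties library quality to the hairpin.

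The second pattern is that 85.3% of hypoxia-only regions were also not called with shZHX2, 29.8 points above matched shared regions. Regions called by chance in the hypoxia list, which both comparisons use, are a candidate explanation. With the roles exchanged, normoxia-only regions were not called with shZHX2 in 87.2%, 25.6 points above their matched regions, but sites that truly close in hypoxia would give this too, so the exchanged value decides nothing. Simulated unchanged lists gave 31.7 and 32.5 points, so the difference alone does not call for sites that open in hypoxia through ZHX2. Their noise was set from the overlaps of the same lists and would take in real changes, so the explanation is left open.

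The third pattern is the gathering of shZHX2-only regions at 15 of 30 luminal genes. For weak regions near the threshold, 19 regions stood where 10.8 were expected by score (percentile 99.9). With lists of equal length, 29 stood where 21.96 were expected (percentile 98.8), and the member count lay at percentile 92.7. By its rule the score-based percentile goes against weak regions as the whole cause. It cannot decide this, because the score-based count put 11 of 56 combinations outside the central 95%. The luminal list was also singled out by its percentile among these same regions. Chance among the percentiles looked at remains open. Outside the central 95% lay 3 of 56 planned percentiles, where 2.80 would if they were spread evenly. At least 1 as far out would turn up in 13.6% of repeats if they were also independent. Both values are approximate, because some small counts cannot reach the lower tail. Of the 19 regions, 14 were also called in normoxia (73.7%, 51.2 to 88.2), against 55.1% of all shZHX2-only regions, a share inside that interval, so no biological reading is put forward.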
